A study of Caenorhabditis elegans with 8 samples.

How the data were processed

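The series holds 8 RNA-seq libraries from Caenorhabditis elegans grown in synchronized liquid culture and collected as young adults. They form 4 groups of 2 libraries: wild type and CstF50 RNAi, each in poly(A)-selected RNA and in rRNA-depleted total RNA. The headers of the poly(A) values place wild type on the empty RNAi vector. CstF50 is a subunit of the cleavage stimulation factor, which acts in 3' end formation of mRNA, and its worm gene is cpf-1. Groups were taken from the sample titles. RNA was extracted with Trizol, and the authors named the genome build ce10 and the tools Bowtie and DESeq, without versions, per the submitters' processing notes. The counter, the annotation and the filters are not given in the sources used here.

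The authors deposited 2 tables, both of their own comparisons and without a column per library. In the poly(A) table the authors give 1 FPKM (fragments scaled to transcript length and to mapped fragments) per gene for each group, per the file headers, with a p-value and a q-value in the layout of Cuffdiff. Its group columns are headed by the wild-type strain with the empty vector L4440 and by cpf-1 RNAi. In the rRNA-depleted table the authors give, per the file headers, the mean normalized count of a condition A and of a condition B, with a p-value and an adjusted p-value. These headers do not say which of A and B is wild type, so no group was assigned, and each value of this table is given as condition B against condition A. The 2 tables were normalized separately and no level was compared across them. Of 44968 rows for poly(A) RNA, 8513 had been tested by the authors (status OK), 35940 had the status NOTEST, none of them above 6.589 FPKM, and the test had failed or been stopped in the others (LOWDATA 488, FAIL 19 and HIDATA 8). The rRNA-depleted table has 25858 rows for 25640 genes, because 118 gene names occur more than once with identical values, and each gene was used once. Gene names and classes came from the table itself or from the RefSeq gene list of assembly WBcel235, which matched 96.9% of the poly(A) and 96.3% of the rRNA-depleted rows. Coordinates are the authors' loci on ce10, written 1-based, and 1 locus can span several genes.

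Genes were called changed where the authors' q-value or adjusted p-value was under 0.05. Fold changes were recomputed from the authors' group values, since their own columns hold infinite entries. For poly(A) RNA the standard error (SE) of a log2 fold change was the size of that fold change divided by the normal deviate of the authors' 2-sided p-value. No other error was available there, and the depth of the poly(A) libraries is unknown. With this error, poly(A) fold changes were also tested relative to the median gene by a normal deviate with Benjamini-Hochberg adjustment, a test chosen after seeing the data. On simulated poly(A) data with 8243 genes it called 41 of 100 genes changed by a log2 fold of 2, 91 of 100 changed by 4 and 9 of 8043 unchanged genes. The simulated errors were drawn with the same SE that the test used, so this does not check whether that SE is right. A gene with an FPKM of 0 in a group is described as listed at 0 and has no fold. In rRNA-depleted RNA a mean of 0 was replaced by the floor of 3 counts over both libraries of the condition (3.04 normalized counts in A and 0.58 in B), and such a fold is a lower bound that covers counting error only. The p-values of single genes rest on 2 libraries per group. The spread between these libraries may be technical, because no label says that they came from separate cultures. Fisher's exact tests were run across genes and measure no spread between libraries.

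Each mean of the rRNA-depleted table is a sum of 2 whole counts, each divided by 2 times its library's size factor. This allowed whole counts per library to be recovered for 25479 of 25640 genes in A and 25401 in B, and for 100.00% of the means up to 1000. Only solutions that matched the printed digits within 0.6 units of the last digit and were unique were used, and means above 30000 were not searched. The size factors came out at 0.7388 and 0.2491 in A and 3.632 and 1.541 in B. The recovered counts summed to 8287830 and 2852379 in A and to 35715235 and 15088069 in B, over genes that hold 12.1% of the normalized counts of A and 42.8% of those of B. These sums leave out the most abundant genes and are not the depth of the libraries, which was not compared between A and B. On simulated means 100.00% of the values were recovered. The simulated means did not extend up to 30000, so they do not check the highest recovered counts. In B 175 genes had more than 1 solution and were not recovered. The chi-square per degree of freedom between the libraries was 4.73 in A and 38.5 in B, so the libraries of a condition differed by more than sampling noise. It grows with the number of counts and does not show that B varied more. The standard deviation of the log2 difference between libraries was 0.64 in A and 0.33 in B, and it depends on the counts too. As an alternative chosen after seeing the data, limma-voom was run on the recovered counts of 16349 genes with at least 10 normalized counts in the higher condition. In simulated counts for that comparison, over 16349 genes, it recovered 39 of 100 genes changed by a log2 fold of 1. Of 100 changed by 2 it recovered 97, and 7 calls were false. Those counts were drawn with the same spread for every gene, which was assumed and not estimated from these libraries. So they do not show how many of the real calls are false.

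Changes were also summarised over 22 gene lists that had been fixed before the data were examined. They cover the CstF subunits, other 3' processing factors, histones, spliced leader (SL) RNA genes, splicing factors, ribosomal proteins, proteasome subunits, cytosolic heat shock proteins, unfolded protein response genes, detoxification enzymes, innate immunity genes, the pals family, RNAi factors, vitellogenins, oocyte and germline genes, sperm genes, collagens and cuticle genes, muscle, neuron and intestine genes, hypodermis and molting genes, and lipid metabolism genes. A list's median log2 fold change was placed among the medians of 10000 random lists of the same size, matched on mean expression. A percentile under 2.5 or above 97.5 is called outside the random range. This describes these libraries only, since genes are not replicates. On simulated poly(A) data with 8243 genes, 13 of 200 unchanged lists of 30 genes and 195 of 200 lists shifted by a log2 fold of 1 fell outside. Counts of called members are given over all genes and adjusted over the list alone. Genes with a same-strand upstream neighbour within 1000 bp were compared with genes whose neighbour was farther, by the same matching and with protein-coding genes of WBcel235, whose annotation also gave gene lengths.

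The rule for the genes named was fixed at the same time. It takes cpf-1, cpf-2 and suf-1, the 8 largest rises and 8 largest falls among called genes with at least 5 FPKM or 50 normalized counts in the higher group, and up to 3 called members of each list with the largest fold change, where genes at 0 in 1 group rank first by their level in the other. Near-identical copies (histone, msp, 5S rRNA and SL1 RNA genes) share reads and their single values are uncertain, as are those of overlapping genes. In the alternative that counted families once, all histone genes formed 1 entry with their mean FPKM, as did all msp genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1. Alternatives were a threshold of 0.01, a minimum fold of 1.5, filters on low values, a pseudocount of 1, recomputed adjustment, families counted once, protein-coding genes alone, recentring on the median gene, leaving out 235 protein-coding genes of the rRNA-depleted table that overlap an RNA gene with at least 0.2 of their mean, and the left-out libraries among the recovered counts.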

Results

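The study measured RNA in young adult C. elegans in which CstF50, a subunit of the cleavage stimulation factor, had been targeted by RNAi, and in wild-type animals. The headers of the poly(A) values place wild type on the empty vector. Poly(A)-selected and rRNA-depleted RNA were each sequenced in 2 libraries per group, 8 libraries in all. The series addresses where RNA polymerase II and CstF subunits sit on genes and operons, and these libraries ask which transcripts differ when CstF50 is targeted. The authors' deposited tables give group values and tests. The rRNA-depleted table names its conditions only A and B, so its differences have a size but no assigned treatment. Recovered counts per rRNA-depleted library ran from 2852379 to 35715235 but leave out the most abundant genes, and the depth of the poly(A) libraries is unknown.

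The target gene cpf-1 was not lower in the RNAi group of the poly(A) libraries. In the authors' deposited table it had 50.5 FPKM in wild type and 67.8 FPKM in CstF50 RNAi, a log2 fold change of 0.42 (implied SE 0.59) with a q-value of 0.613. Relative to the median gene, whose log2 fold change was -0.90, it was 1.32 (adjusted p = 0.228). Its value is given within a locus on chromosome II from 8594298 to 8602421 (ce10) that also covers neighbouring genes. The genes of the other subunits did not pass the test either: cpf-2 (CstF64) had 70.8 and 54.6 FPKM and suf-1 (CstF77) had 12.6 and 8.76 FPKM in the authors' deposited table. In rRNA-depleted RNA cpf-1 was 5.11-fold higher in condition B, with 1695 and 8662 normalized counts in the authors' deposited table and an adjusted p-value of 0.00296. The recovered counts of cpf-1 were 1220 and 433 in the libraries of A and 25338 and 15942 in those of B. The cpf-2 and suf-1 means differed little there, at 550 and 629 and at 1392 and 1622 normalized counts, both with an adjusted p-value of 1 in the authors' deposited table. The poly(A) libraries labelled CstF50 RNAi therefore carried no lower cpf-1 value to check their label, and whether reads from the RNAi trigger were counted was not analysed here.

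In poly(A) RNA, genes for cuticle collagens and for sperm proteins were higher in the group labelled CstF50 RNAi, in which cpf-1 was not lower, while most tested genes had lower FPKM there. The collagen gene dpy-13 (chromosome IV, 4235607 to 4236699, ce10) had 0.356 FPKM in wild type and 307 FPKM in RNAi, a log2 fold change of 9.75 (implied SE 1.37) with a q-value of 2.49e-09 in the authors' deposited table. The intestinal peptide transporter gene pept-1 (chromosome X, 6456650 to 6461833) was 10.3-fold lower in RNAi, a log2 fold change of -3.37 (implied SE 0.82) with a q-value of 0.0021 in the authors' deposited table. The authors' deposited table called 1427 of 8513 tested genes, 266 higher and 1161 lower in RNAi. The median log2 fold change of the 8244 tested genes with both values above 0 was -0.90, and with fold changes taken relative to that median 506 genes passed, 464 higher and 42 lower.

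The other largest rises in poly(A) RNA, all called in the authors' deposited table, were mainly collagens. They were col-162 with 0.0444 and 33.1 FPKM, col-73 with 0.633 and 350 FPKM, dpy-5 with 0.708 and 188 FPKM, and the gene Y82E9BR.20 with 0.0498 and 13.5 FPKM in wild type and RNAi. The genes col-88, col-63 and H27M09.7 were listed at 0 in wild type and at 57.8, 18.6 and 1922 FPKM in RNAi, and an exact 0 in this table can be a failed estimate. The largest falls were in genes known mostly by sequence name. In the authors' deposited table C01G10.6 fell from 42.0 to 0.988 FPKM, EGAP4.1 from 71.1 to 2.07, Y47D7A.12 from 45.4 to 1.54, F36H1.11 from 15.8 to 0.581, C46G7.5 from 42.0 to 1.70, F44G3.10 from 17.9 to 0.759, T25C12.3 from 12.4 to 0.597 and E02H9.7 from 79.8 to 3.89. Relative to the median gene, Y47D7A.12 and F36H1.11 no longer passed (adjusted p = 0.0646 and 0.174). Adjusted over all rows of the authors' deposited table, untested ones included, Y82E9BR.20 and F36H1.11 no longer passed (adjusted p = 0.195 and 0.14). Rows without a test enlarge this adjustment, so such a loss is partly built into it.

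**Figure D1:**
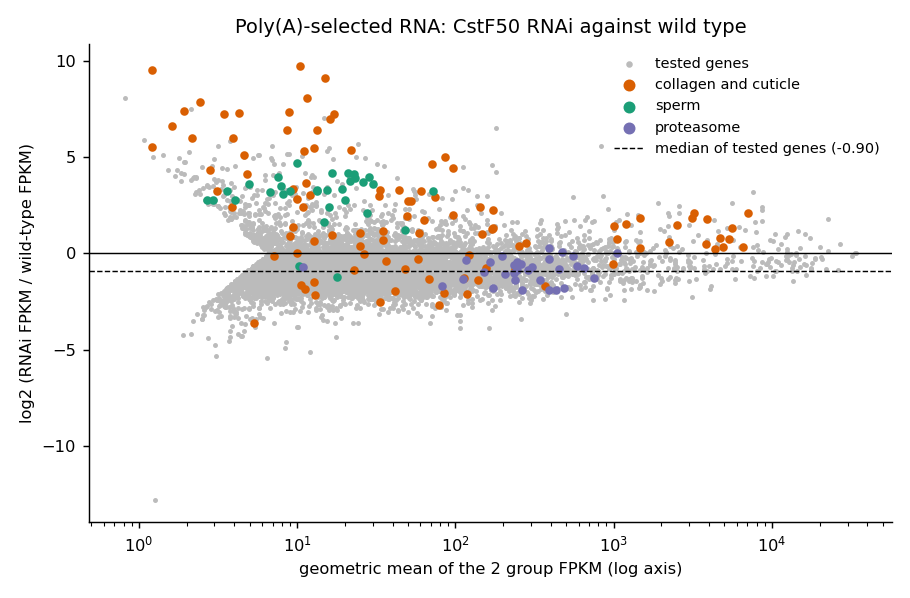
Each point is a tested gene of the poly(A) table with both values above 0; the horizontal axis (log scale) is the geometric mean of the 2 group FPKM and the vertical axis the log2 ratio of CstF50 RNAi to wild type. Collagen and cuticle genes (orange) and sperm genes (green) lie mostly above the dashed median of -0.90, and proteasome genes (purple) lie near it.

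Among the collagen and cuticle genes of the poly(A) table, 46 of 105 tested members rose, 7 fell and 52 did not pass, and adjusted over the list alone 53 rose and 7 fell. Relative to the median gene 55 were higher and 1 lower, and the list's median log2 fold change of 1.49 lay at percentile 100 of random lists. Of 32 tested sperm genes 15 rose, none fell and 17 did not pass over all genes, against 22 higher and 1 lower adjusted over the list alone and 20 higher relative to the median gene. Their median log2 fold change was 3.26, also at percentile 100. In the authors' deposited table the major sperm protein genes msp-57 and msp-40 went from 1.96 to 50.6 FPKM and from 4.93 to 88.7 FPKM. The sperm gene ssp-9 went from 3.90 to 71.3 FPKM there. Adjusted over all rows, untested ones included, ssp-9 did not pass (adjusted p = 0.109). The copies of the msp family are near identical and their single values are uncertain.

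Innate immunity genes moved both ways in poly(A) RNA, with 10 of 74 tested members higher and 8 lower, 10 and 9 adjusted over the list alone, 18 and 2 relative to the median gene, and a median at percentile 100 of random lists. The lysozyme gene ilys-2 rose 30.4-fold and the antimicrobial peptide gene cnc-6 from 3.11 to 48.1 FPKM in the authors' deposited table, and the lectin gene clec-222 fell from 15.5 to 1.25 FPKM. Adjusted over all rows, untested ones included, ilys-2 did not pass (adjusted p = 0.178). The histone list had 1 member higher and 2 lower of 24, the same adjusted over the list alone. Relative to the median gene 2 were higher and 0 lower. The list's median lay at percentile 99.54. With all histone genes merged into 1 entry by their mean FPKM the percentile was 73.44. That percentile rests on a single value, so it cannot show whether near-identical copies made the difference. The linker histone gene his-24 rose from 200 to 1518 FPKM in the authors' deposited table, a log2 fold change of 2.92 (implied SE 0.47), and his-59 and his-37 fell but did not pass relative to the median gene. Of 17 lipid metabolism genes 2 rose and 1 fell, the same adjusted over the list alone and 3 and 0 relative to the median gene, with a median at percentile 98.97. The acyl-CoA synthetase gene acs-2 rose from 3.48 to 21.4 FPKM and the desaturase gene fat-2 from 197 to 595 FPKM in the authors' deposited table, while the fatty acid elongase gene elo-5 fell from 292 to 49.2 FPKM and did not pass relative to the median gene (adjusted p = 0.0616). Adjusted over all rows, untested ones included, acs-2 did not pass (adjusted p = 0.104).

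Of 73 ribosomal protein genes 6 rose in poly(A) RNA, 4 adjusted over the list alone, and 17 were higher relative to the median gene. The largest changes among the called members in the authors' deposited table were in rpl-25.1, from 768 to 4749 FPKM, rpl-26, from 2246 to 13797 FPKM, and rpl-11.1, from 2340 to 7836 FPKM. The list's median was at percentile 89.06, within the random range. Detoxification genes went both ways, 4 higher and 7 lower of 58, and 4 and 10 adjusted over the list alone, at percentile 35.87, but 5 higher and 2 lower relative to the median gene. In the authors' deposited table the superoxide dismutase gene sod-3 rose 20.6-fold, and the glutathione transferase gene gst-27 and the cytochrome P450 gene cyp-35C1 fell from 325 to 35.3 and from 43.2 to 4.79 FPKM. Muscle genes had 1 member higher and 1 lower of 18, and the same adjusted over the list alone, at percentile 83.50. These were the troponin gene unc-27, from 586 to 1827 FPKM, and the pharyngeal myosin gene myo-2, from 15.6 to 2.86 FPKM in the authors' deposited table, and myo-2 did not pass relative to the median gene (adjusted p = 0.131).

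In several lists of poly(A) RNA every called member was lower, while the list medians lay within the range of random lists. Proteasome subunits fell in 10 of 31 genes, 11 adjusted over the list alone, among them rpt-3, rpn-10 and pas-4 with log2 fold changes of -1.88 each in the authors' deposited table. None of the 31 passed relative to the median gene, and their median was at percentile 37.22. The called members were 3 of 22 splicing genes (snr-3, rsp-7 and snr-5), 3 of 7 unfolded protein response genes (dnj-10, hsp-60 and hsp-4), 3 of 31 oocyte and germline genes (glp-1, syp-2 and mex-5) and 2 of 19 RNAi factors (rde-1 and mut-16). Adjusted over the list alone these counts were 3, 3, 3 and 8. Also lower were 3 of 37 neuron genes (flp-22, egl-3 and ida-1), 2 adjusted over the list alone, and 3 of 18 intestine genes (pept-1, act-5 and cpr-4), 3 adjusted over the list alone. A single member was lower in the lists of 15 3' processing factors (cpsf-2), 6 vitellogenins (vit-1) and 10 hypodermis and molting genes (nhr-23), the same adjusted over the list alone. Relative to the median gene pept-1 was the 1 named member in these lists that still passed as lower, and 2 other intestine genes passed as higher. The medians of these lists were at percentiles 42.53 (splicing), 47.72 (unfolded protein response), 11.51 (oocyte), 29.64 (RNAi), 33.96 (neuron), 47.43 (intestine), 68.57 (3' processing), 66.15 (vitellogenins) and 55.48 (molting), all within the random range. No member was called by the authors' Cuffdiff test, over all genes or adjusted over the list alone, among the 3 CstF genes at percentile 83.75 and the 3 tested heat shock genes at percentile 54.81, and 0 of them had an unadjusted p under 0.05. The 2 tested SL RNA genes had no fold, and the pals family was not analysed here.

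In rRNA-depleted RNA, most sperm genes and many collagen genes were higher in condition B, and 11 of 76 ribosomal protein genes were lower (8 of 67 with genes that overlap RNA genes left out). A run of neighbouring 5S rRNA and SL1 RNA genes was at exactly 0 in B, while T27C5.18, a 5S gene outside the run chosen after its values were seen, had 593152 normalized counts in B and 4880485 in A in the authors' deposited table. The collagen gene col-175 had no counts in A and 715 normalized counts in B, at least 236-fold higher with an adjusted p-value of 2.48e-45 in the authors' deposited table. Its recovered counts were 0 and 0 in the libraries of A and 2846 and 997 in those of B. The authors' deposited table called 2130 of 25640 genes, 1420 higher and 710 lower in B. With fold changes taken relative to the median log2 of 0.08 the split was 1290 higher and 1003 lower. That split used the SE implied by the authors' p-value, as in poly(A) RNA. It assumes a normal test of the log2 fold change, which was not checked. By limma-voom on the recovered counts 5849 genes were called.

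The other largest rises in B, at 0 in A, included sperm and collagen genes in the authors' deposited table. They were ssq-4 at 624 normalized counts (at least 205-fold), kin-24 at 589 (at least 194-fold), C35D10.2 at 516 (at least 170-fold), msp-36 at 456 (at least 150-fold), col-17 at 398 (at least 131-fold), and the similar genes col-126 and col-127 at 382 each (at least 126-fold). Of 58 sperm genes 37 were higher in B and none lower, 39 adjusted over the list alone, and of 176 collagen and cuticle genes 76 were higher and none lower, 86 higher and 1 lower adjusted over the list alone. Their median log2 fold changes of 4.42 and 1.43 were both at percentile 100, and with genes at 0 left out the medians were 5.07 and 1.38. The sperm genes msp-3 and gsp-3 were at least 71.8-fold and at least 30.9-fold higher in the authors' deposited table.

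The 8 largest falls in B were all 5S rRNA genes of 1 array on chromosome V. In the authors' deposited table Y102A5D.5, Y102A5D.6, Y102A5D.7, Y102A5D.8, Y102A5D.9, Y102A5D.10, ZK218.12 and ZK218.20 had between 5055540 and 5653096 normalized counts in A and 0 in B. The SL1 RNA genes sls-1.8, sls-1.9 and sls-1.7 had 981924, 961503 and 784225 in A and 0 in B. SL1 is the short leader that is spliced onto the 5' end of many worm mRNAs. Of 30 SL RNA genes 13 were lower and none higher, the same adjusted over the list alone, with a median log2 fold change of -3.27 at percentile 0.00, and -1.66 with genes at 0 left out. Of the 13, 11 lie in the run at exactly 0 in B. Copies of these genes share reads, and their values are uncertain. Every one of the 8 5S genes and 3 SL1 genes named here lies in 1 unbroken run of 27 genes at 0 in B.

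**Figure D2:**
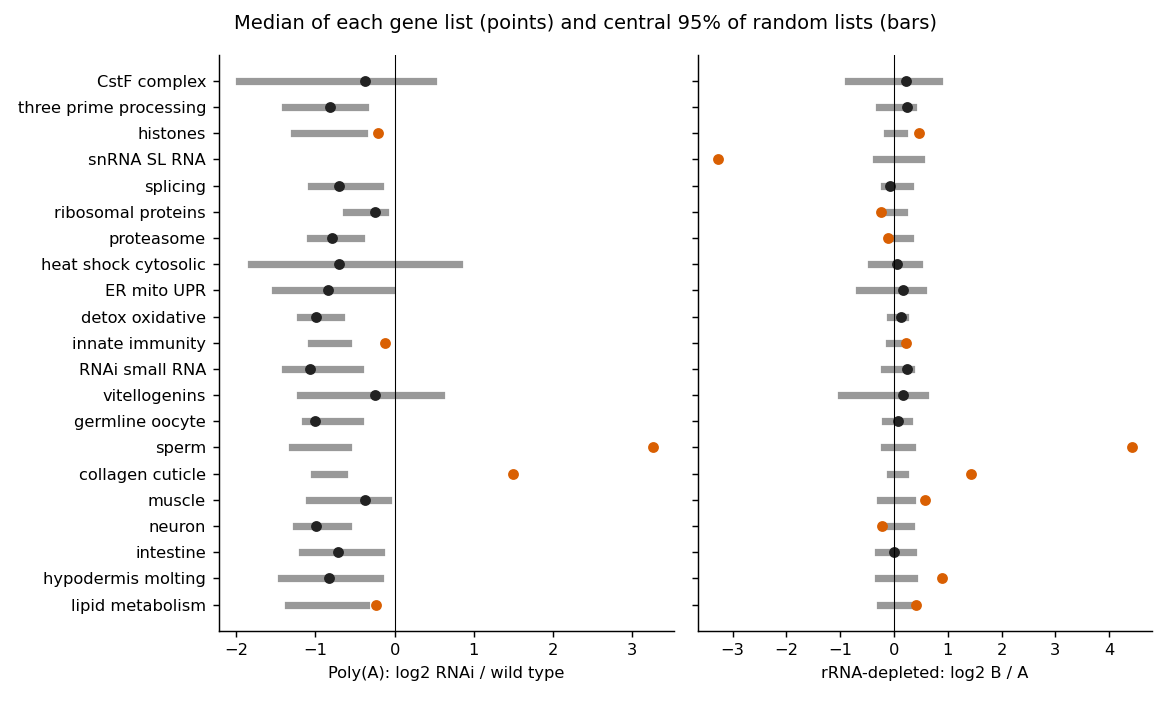
Points show each list's median log2 fold change, RNAi over wild type in poly(A) RNA on the left and condition B over A in rRNA-depleted RNA on the right, and bars the central 95% of 10000 random lists matched on expression. Orange points lie outside the bar; sperm reached 3.26 and 4.42, collagen and cuticle 1.49 and 1.43.

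Outside the run at 0, the only ribosomal RNA gene listed was the 5S gene named above. It took 16.44% of the normalized counts of A and 2.59% of those of B, and protein-coding genes took 61.74% and 84.74%. Its share is not that of all ribosomal RNA, and a fall in it raises the other shares. Muscle genes were higher in B in 9 of 21 members with none lower, 11 adjusted over the list alone, at percentile 99.96. The giant sarcomere gene unc-22 had 1646 normalized counts in A and 5509 in B in the authors' deposited table, and unc-54 and unc-89 were 3.05-fold and 2.93-fold higher. Histones were higher in 16 of 70 genes with none lower, the same adjusted over the list alone, at percentile 100. With genes that overlap RNA genes left out, 12 of 65 were higher, also at percentile 100. Near-identical histone copies share reads, and counting families once was not run for rRNA-depleted RNA. There his-24 had 225 and 930 normalized counts, and his-43 and his-44 were 2.87-fold and 2.5-fold higher in the authors' deposited table. Hypodermis and molting genes were higher in 6 and lower in 2 of 22, 7 and 3 adjusted over the list alone, at percentile 100, with qua-1, fbn-1 and mlt-11 at 14.9-fold, 4.50-fold and 3.99-fold higher in the authors' deposited table. By limma-voom on recovered counts the log2 fold change of qua-1 was 3.63, and 4.56 without library 1 and 3.19 without library 2 of A. Lipid metabolism genes were higher in 6 and lower in 2 of 24, the same adjusted over the list alone, at percentile 98.46 (97.00 with genes under 10 normalized counts left out and 96.61 without genes that overlap RNA genes), and cpt-3, acs-2 and fat-5 were 15.2-fold, 4.99-fold and 2.68-fold higher in the authors' deposited table. That of cpt-3 was 4.36 by limma-voom, 2.84 without library 1 of A (adjusted p = 0.05) and 5.15 without library 2 of A. Innate immunity genes were higher in 27 and lower in 8 of 285, 30 and 8 adjusted over the list alone, at percentile 97.62 (95.72 with genes at 0 left out), with clec-79, clec-123 and ilys-3 at 0 in A and at 96.7, 73.6 and 52.3 normalized counts in B in the authors' deposited table.

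Ribosomal protein genes were lower in B in 11 of 76 members with none higher, the same adjusted over the list alone, at percentile 0.05. Short RNAs abundant in A were lower in B as well. The 190 other RNA genes of up to 200 bp and above 1000 normalized counts in A had a median log2 fold change of -1.41. Choosing genes by their level in A favours lower values in B. Of 78 microRNA genes 0 were called, and their normalized counts summed to 2784 in A and 2715 in B. In the authors' deposited table rps-12 had 24422 normalized counts in A and 7285 in B, and rps-29 and rps-13 were 2.34-fold and 2.25-fold lower. All 3 overlap small nucleolar RNA genes on the same strand, chosen after their values were seen: F54E7.10 in rps-12 had 19433 and 2964.84 normalized counts, C16A3.11 in rps-13 had 5552.78 and 1612.18, and B0412.7 in rps-29 had 5328.36 and 1317.17 in the authors' deposited table. Their folds are therefore uncertain as values of ribosomal protein mRNA. With protein-coding genes that overlap such RNA genes left out, 8 of 67 were lower and the list was at percentile 0.07. Neuron genes were lower in 3 of 46 with none higher, the same adjusted over the list alone, at percentile 2.00 (2.62 with genes at 0 left out). These were unc-31, rab-3 and snt-1, at 5.02-fold, 2.67-fold and 2.56-fold lower in the authors' deposited table. There unc-31 had 143617 normalized counts in A and 28606 in B, and the snRNA genes ZK897.3 and ZK897.4 inside it, chosen after their values were seen, had 47727.3 and 8939.93 and 95188.1 and 18634.4. Its value cannot be read as that of the neuron gene, and without overlapping genes 2 of 44 were lower, at percentile 2.09. No proteasome gene of 32 was called by the authors' DESeq test over all genes or adjusted over the list alone. Of these, 6 had an unadjusted p under 0.05 and limma-voom called 1 higher and 11 lower, and their median of -0.11 was at percentile 2.23 (3.47 on the log2 scale with a pseudocount of 1).

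**Figure D3:**
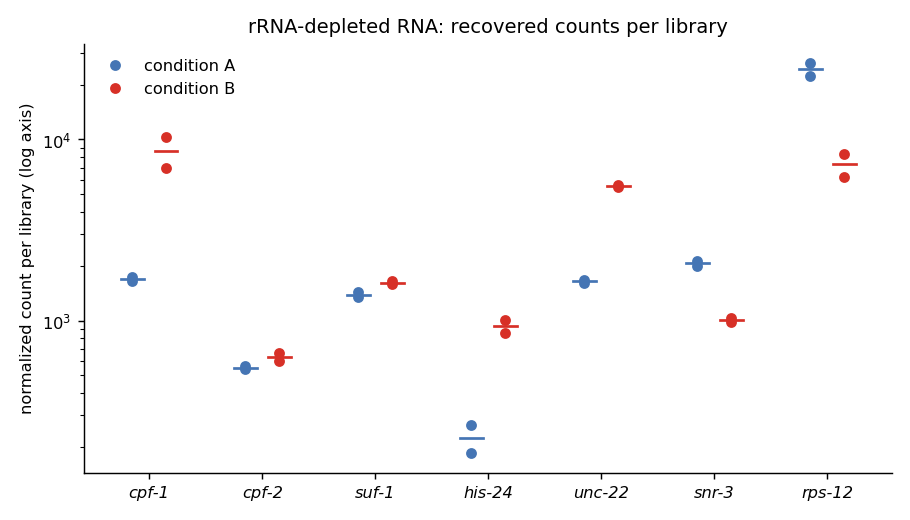
Points are the normalized counts of single rRNA-depleted libraries (vertical axis, log scale), recovered from the condition means, for 7 genes, with condition A in blue, condition B in red and bars at the condition mean. The 2 libraries of each condition lie closer together than the conditions do for cpf-1, his-24, unc-22, snr-3 and rps-12, which overlaps a small nucleolar RNA gene.

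The medians of the other lists stayed within the random range in rRNA-depleted RNA. Intestine genes, at percentile 30.86, had 1 member higher and 6 lower of 20, 3 and 6 adjusted over the list alone, and cpr-3, pept-1 and pho-1 were 2.26-fold, 2.19-fold and 2.13-fold lower in B in the authors' deposited table. Detoxification genes, at percentile 75.89, had 19 higher and 9 lower of 191, 21 and 10 adjusted over the list alone, with gst-9 and gst-24 9.85-fold and 9.08-fold higher and gst-11 6.74-fold lower in the authors' deposited table. The gst-9 gene overlaps the sperm gene msp-33 on the other strand, chosen after its values were seen, which was 21.82-fold higher, so the value of gst-9 is uncertain. Oocyte and germline genes, at percentile 49.48, had 3 higher of 31 (cav-1, syp-1 and glp-1), and 3 higher and 1 lower adjusted over the list alone. A single member was higher among 3 CstF genes (cpf-1, percentile 67.78), 10 heat shock genes (hsp-70, percentile 50.07), 7 unfolded protein response genes (xbp-1, percentile 68.42), 22 RNAi factors (dcr-1, percentile 91.28) and 6 vitellogenins (vit-2, percentile 67.40). Adjusted over the list alone these were 1, 1, 2 and 1 higher, and 2 higher and 1 lower for the vitellogenins. Of 22 splicing genes snr-3 alone was lower, also adjusted over the list alone, at percentile 15.81. None of 15 3' processing genes was called over all genes or adjusted over the list alone, at percentile 89.39, where 2 had an unadjusted p under 0.05 in the authors' DESeq test and limma-voom called 5 higher and 2 lower.

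Among the 8446 genes tested in both of the authors' deposited tables, genes higher in poly(A) RNAi were often higher in condition B. Of 266 genes called higher in RNAi and 674 called higher in B, 161 were shared, against 21.2 for independent lists (Fisher's exact test across genes, 2-sided p = 1.32e-112). Of 1158 called lower in RNAi and 432 called lower in B, 139 were shared against 59.2 (Fisher's exact test, p = 2.92e-24). The opposite pairings were below the value for independent lists, with 4 genes against 13.6 (p = 0.00411) and 32 genes against 92.4 (p = 3.65e-15), both by Fisher's exact test. With poly(A) fold changes relative to the median gene, 221 were higher in both and 20 lower in both. Fold changes of 8069 genes had a Spearman rho of 0.323 across genes, and genes are not independent replicates. As A and B are unassigned, the pairing does not say whether the fractions moved the same way under RNAi.

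Genes within 200 bp of a same-strand upstream neighbour had slightly lower log2 ratios than matched genes in both tables. So did genes with a close upstream neighbour on the opposite strand. The same-strand comparison bears on whether reads from an upstream gene extend into the next one. In poly(A) RNA the median log2 fold change of 2349 genes with such a neighbour within 1000 bp was -0.91, a difference of -0.03 from matched genes at percentile 2.83, within the random range. For the 1067 genes within 200 bp it was -0.95, a difference of -0.07 at percentile 1.15. The 639 genes beyond 200 but within 500 bp had the same median and difference, at percentile 2.81, and the 1282 genes beyond 200 but within 1000 bp had -0.87, at percentile 56.15. In rRNA-depleted RNA the median of 4488 genes was 0.02, a difference of -0.06 at percentile 0.00. For 1632 genes within 200 bp it was -0.05, a difference of -0.14. The 2856 genes beyond 200 but within 1000 bp had a median of 0.08, at percentile 62.15, within the random range. With A and B unassigned, these differences do not say which treatment had the lower value. Genes with an upstream neighbour within 1000 bp on the opposite strand had medians of -0.91 in poly(A) RNA and 0.04 in rRNA-depleted RNA. Their differences from matched genes were -0.10 and -0.11, each at percentile 0.00, against -0.03 and -0.06 for the same-strand genes. The pools of farther genes were unlike, with 3558 poly(A) genes here and 5221 for the same-strand genes. Within 500 bp the same-strand and opposite-strand differences were -0.07 and -0.09 in poly(A) RNA. In rRNA-depleted RNA they were -0.09 and -0.06. Which kind differed more depended on distance and RNA fraction, so these values do not set the 2 kinds of neighbour apart.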

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

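The tests by expression level, of summed FPKM and of short RNAs and the run at 0, and the use of the planned lists and overlap to weigh explanations, were chosen after the results were seen. The authors' deposited table has 37 genes of at least 5 FPKM whose poly(A) test failed or was stopped by too few or too many data, and 5 of them were higher in CstF50 RNAi than in wild type and 32 lower. The ribosomal protein genes rpl-31 and rps-3 had 17974 against 7092.5 FPKM and 10431 against 1972.9 FPKM. F36A2.7 had 2308.2 against 1491.8 FPKM, Y69A2AR.3 had 1393.2 against 598.85 FPKM and W10G11.2 had 5.6631 against 2.9674 FPKM. Of the 32 that were lower, those with the most FPKM in wild type were Y37E3.8 with 29024 in RNAi against 45134, cyn-3 with 2744 against 4649, eef-2 with 1726 against 3984, ZK813.7 with 997 against 3320 and rrn-3.56, listed at 0 against 1879. A further 717 genes of at least 5 FPKM were left untested by the authors under another status, 179 of them higher and 538 lower in RNAi. These values stand outside the report's comparisons and were not tested.

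The median poly(A) gene had a log2 fold change of -0.90 in CstF50 RNAi. A single scaling factor as the whole cause is argued against by the levels: genes above 1000 FPKM had a median of -0.34 (bootstrap interval -0.45 to -0.23), against -0.93 (-0.97 to -0.89) for genes of 10 to 30 FPKM. A larger share of reads in a few abundant genes cannot be told apart, because FPKM times length summed over all genes itself moved by -0.33, and by -0.51 outside the 100 largest. An effect of CstF50 RNAi on most mRNAs stays open and untested, since no spike-in value was used here.

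In condition B of the rRNA-depleted RNA, 26 genes above 1000 normalized counts in A were at exactly 0, and no gene showed the reverse. Loss with other short RNAs is argued against, since 0 of 190 other RNA genes of up to 200 bp and above 1000 in A were at 0 in B (median log2 -1.41). The genes at 0 formed an unbroken run of 27 genes, including a pseudogene, while a 5S gene elsewhere kept 593152 normalized counts in B (4880485 in A). This is consistent with reads of that interval having been left out of the B counts. No biological explanation was tested.

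Collagen and sperm genes were higher in poly(A) RNAi and in condition B. Younger animals in the RNAi cultures are a candidate explanation, because sperm are made in the last larval stage and collagens before molts. Oocyte genes at percentile 11.51 and vitellogenins at percentile 66.15 were within the random range, which a small share of younger animals would also give, so the 2 cannot be told apart. Hypodermis and molting genes did not rise with the collagens in poly(A) RNA, with 0 higher and 1 lower of 10, at percentile 55.48. In rRNA-depleted RNA they were at percentile 100, with 6 higher and 2 lower in B of 22. An effect of CstF50 RNAi itself is also open: 161 genes were higher in both, but A and B are unassigned and each culture differs by its RNAi.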

How the results depend on the processing

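No paired analysis was possible because neither table has values with replicate numbers. So no replicate block was run, no poly(A) library was left out and no pseudocount per library was used. A pseudocount of 1 on the group values was run. TMM and DESeq2 were planned for deposited counts and were not run, on the recovered counts either. The tests on recentred poly(A) values, protein-coding genes, genes at 0 left out, overlapping genes left out and recovered counts were chosen after the data were seen, and the others were planned. The 1427 poly(A) calls (266 higher, 1161 lower) became 500 (140 and 360) at a threshold of 0.01, 492 (139 and 353) when adjusted over all rows including untested ones, and 506 (464 and 42) relative to the median gene. The low-value filters removed no tested poly(A) gene and no rRNA-depleted call and say nothing about these counts. The 710 rRNA-depleted calls lower in B became 438 at 0.01 and 672 without genes that overlap RNA genes. By limma-voom on recovered counts the rRNA-depleted calls were 5849 (3252 higher, 2597 lower), and with each library left out, where a lone library is assumed to vary like the others, 2598 (1323 and 1275) without library 1 of A, 4643 (2607 and 2036) without library 2 of A, 6726 (3869 and 2857) without library 1 of B and 7583 (4232 and 3351) without library 2 of B, where suf-1 passed (0.23, adjusted p = 0.0257). The library numbers only name recovered libraries. Of 2029 called genes with recovered counts, 1655 kept call and direction with each library left out. The 300 genes shared between tables in the pairing of RNAi with B became 133 at 0.01 and 562 with limma-voom calls. The poly(A) neighbour difference became -0.07 at 500 bp, outside the random range. Relative to the median gene cpf-2 and suf-1 reversed in poly(A) RNA, to 0.52 and 0.37, both still uncalled, and 28 of 59 named genes lost their call, as did 19 of 59 adjusted over all rows and 18 of 59 at 0.01. In rRNA-depleted RNA 4 of 59 lost theirs at 0.01. Except where its construction shows it, the cause was not tested. Size factors were smaller in A, so a gene at 0 there can have up to 3.04 normalized counts, against 0.58 in B.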

Other observations

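The values in this part were chosen after the data were seen, except the poly(A) call of rpl-26. Of 25640 genes in the authors' deposited table for rRNA-depleted RNA, 710 were called lower in condition B. Outside the run of 27 genes at 0 in B, 30 of 100 small nuclear RNA (snRNA) genes were called, all lower, and 60 of 140 small nucleolar RNA genes were called, 59 of them lower. The other genes of both classes did not pass, and neither class was tested as a list. That run held 11 more called snRNA genes, all SL1, and 68.41% of all normalized counts in A. Outside the run, the only ribosomal RNA gene listed took 16.44% of normalized counts in A and 2.59% in B. Protein-coding genes took 61.74% and 84.74% there. The share of that single gene is not the share of all ribosomal RNA.

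The ribosomal protein gene rpl-26 lies next to cpf-1 on chromosome II. In the authors' deposited table it rose in poly(A) RNA with a q-value of 0.000491, while in rRNA-depleted RNA rpl-26 had 7930 normalized counts in A and 6250 in B with an adjusted p-value of 0.4715. Among genes with 1 to 10 recovered counts, even counts made up 58.3% and 60.7% in the libraries of A and 53.0% and 52.6% in those of B.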
